A study of Mus musculus with 8 samples.

How the data were processed

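Polyadenylated RNA from the medial prefrontal cortex of mice was sequenced as strand-specific libraries, made with the dUTP method per the labels' protocols. There were 4 libraries labelled Ino80e overexpression and 4 labelled wild type, and groups and replicate numbers were taken from the sample titles. The deposited table holds raw read counts, 1 column per library, for 54446 Ensembl gene identifiers. Trimmomatic 0.39, STAR 2.7.10 and featureCounts 2.0.3 and the mouse builds mm10 and GRCm38 are named in the submitters' processing notes, with neither the role nor the order of each tool. The strand setting of the counting, the annotation release and the handling of reads that map to several places are not given in the sources used here. Without them, reads of overlapping genes, of antisense partners and of near-identical gene copies may be divided in an unknown way. Some such genes are marked as uncertain where they are named, but not all. Kctd13, Coro1a, Uchl5, Homer1 and Erc2, among others, overlap other annotated genes and carry no mark below.

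Gene symbols, coordinates, transcript GC content and length came from the GENCODE annotation of the GRCm38 build, matched by Ensembl identifier. A symbol was found for 54409 identifiers, and 37 had none. Library totals ran from 44762378 to 60490153 counts. No library was a copy of another: the chi-square per degree of freedom between any 2 libraries was at least 9.57, where sampling noise alone gives about 1. All 8 libraries expressed Y-linked genes. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical.

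Low-count genes were removed with filterByExpr, which left 17636 genes, and libraries were scaled by the trimmed mean of M-values (TMM). The main test was edgeR's robust quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) of the libraries labelled overexpression against wild type, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are log2 values, overexpression minus wild type, with their standard errors (SE). Levels are in CPM, read counts relative to the TMM-scaled library size, as mean ± SD over 4 libraries. The common biological coefficient of variation was 12.9%. Ino80e was also tested by an exact two-sided permutation test of log2 CPM over 70 arrangements.

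Gene lists of pathways, complexes and cell types, 33 of them with at least 5 tested members, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. The same test with a correlation estimated from the residuals, and fry, were run beside it. The directional p of fry asks whether a list's genes move one way on balance, and its mixed p whether they change in either direction. Neither compares a list with other genes. Members were also tested with the edgeR p adjusted over the list alone.

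The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named Ino80e, then up to 10 genes per direction with the lowest p among those past the threshold with an ordinary symbol, the 3 largest fold changes per direction among those of at least 1 CPM, and up to 4 members of each list with the lowest p. Of the list members so named, up to 4 per list are given, some are not reported here, and any gene outside the rule is said to be so.

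The alternatives were DESeq2 size factors (RLE) and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit without robust estimation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, and leaving out each library in turn. A correction for GC content was chosen after seeing the data: a spline with 5 degrees of freedom of each library's log2 CPM on transcript GC content, entered as an offset. Leaving out each pair of the libraries labelled overexpression was also chosen after seeing the data.

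The test was tested on simulated data with the means and library sizes of these samples (17367 genes). edgeR found 48% of 50 genes changed 1.25-fold, 84% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 7 false calls in all, against 32 with DESeq2 and 10 with limma-voom. The changed genes had a mean of at least 1 CPM, and all fold changes were simulated at once in a single run. Noise was drawn from edgeR's own dispersions, independently between genes and with no GC trend. Intervals of count ratios are 95% Poisson intervals and cover counting error only, since reads amplified without molecular identifiers are not independent molecules.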

Results

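The series concerns Ino80e, a subunit of the INO80 chromatin remodelling complex that lies in a schizophrenia risk locus on human 16p11.2. Its design text describes adeno-associated virus injected into the medial prefrontal cortex to alter the expression of the risk gene. Poly(A) RNA of this region was measured in 4 libraries labelled overexpression and 4 labelled wild type. Whether the wild-type mice received a control virus is not given in the sources used here. The libraries labelled overexpression held 52665682, 47700489, 60490153 and 49770686 counts, and the wild-type libraries 44762378, 48697238, 55379790 and 49294171, in the order of replicates 1 to 4. The comparison asks which transcripts differ in prefrontal cortex between the group labelled overexpression and the wild-type group.

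Ino80e itself was raised in 2 of the 4 libraries labelled overexpression. Its level was 74.1 CPM in replicate 1 and 45.04 CPM in replicate 4, which is 3.36 and 2.05 times the wild-type mean of 22.0 ± 2.60 CPM (SD, n = 4). Replicates 2 and 3 held 23.4 and 23.3 CPM, inside the wild-type range of 19.5 to 25.5 CPM. Over all 4 libraries labelled overexpression the mean was 41.5 ± 24.0 CPM (SD, n = 4), a log2 fold change of 0.91 (SE 0.42) that did not pass the test (edgeR adjusted p = 0.51). An exact two-sided permutation test of log2 CPM gave p = 0.114, where 0.0286 is the smallest p that 4 against 4 libraries allow. Ino80e (ENSMUSG00000030689) lies on chromosome 7 at 126850960 to 126862377 on the minus strand of GRCm38 and overlaps Hirip3 and Doc2a on the opposite strand, so its counts are uncertain where the counting did not use strand. Because the target level of replicates 2 and 3 does not match their label, every direction below is that of the libraries labelled overexpression against wild type, not that of a measured rise of Ino80e.

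**Figure D1:**
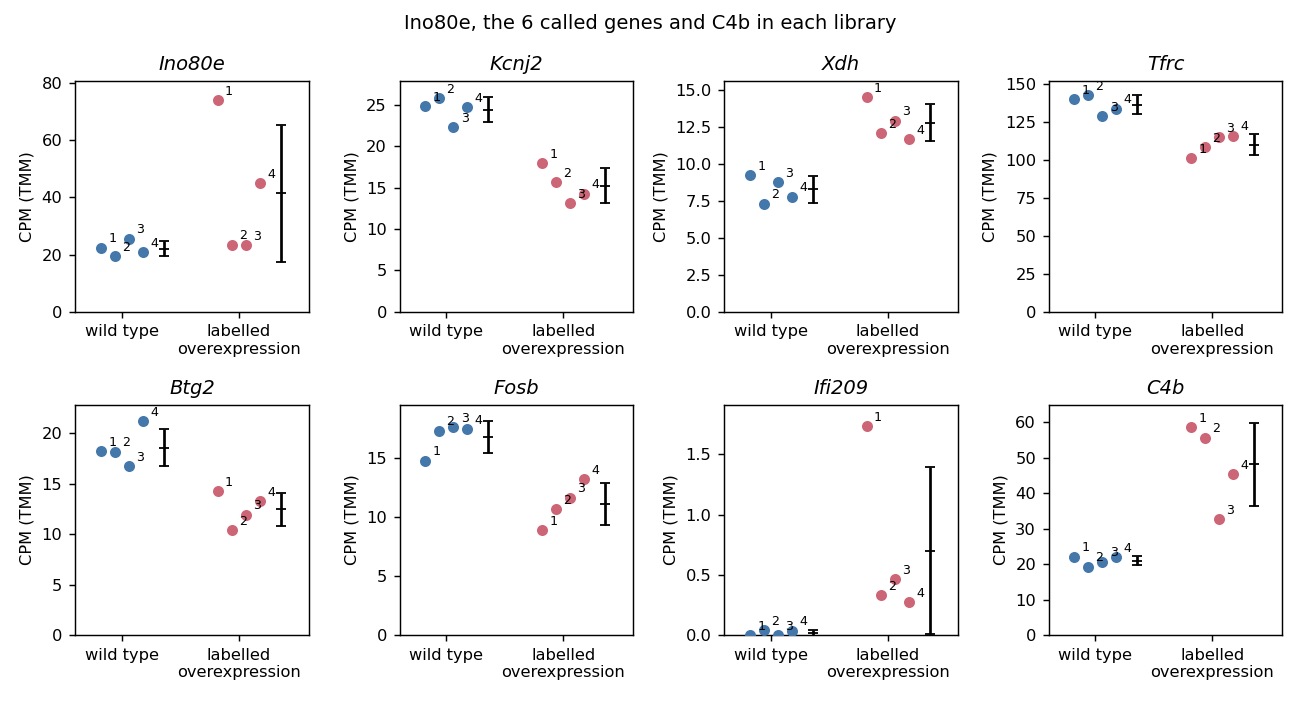
Level of Ino80e, the 6 genes past the threshold and C4b, in CPM after TMM scaling, with 1 point per library numbered by replicate and the mean ± SD of 4 libraries in black. Ino80e stood above the wild-type range only in replicates 1 and 4 of the group labelled overexpression, while Kcnj2 stood at 13.1 to 17.96 CPM in that group and at 22.3 to 25.8 CPM in wild type.

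Of 17636 genes tested, 6 changed, 2 higher and 4 lower in the libraries labelled overexpression. Kcnj2, which encodes an inward-rectifier potassium channel, fell from 24.4 ± 1.51 to 15.2 ± 2.10 CPM (log2 fold change -0.68, SE 0.093, adjusted p = 0.0032). The transferrin receptor gene Tfrc fell from 136 ± 6.21 to 110.0 ± 6.78 CPM (log2 -0.31, SE 0.055, adjusted p = 0.037). The activity-regulated genes Btg2 (log2 -0.58, SE 0.10, adjusted p = 0.037) and Fosb (log2 -0.59, SE 0.11, adjusted p = 0.042) also fell. Xdh, which encodes xanthine dehydrogenase of purine breakdown, rose from 8.27 ± 0.886 to 12.8 ± 1.26 CPM (log2 0.63, SE 0.11, adjusted p = 0.037). Xdh overlaps another annotated gene on the same strand, so its counts are uncertain. Ifi209, of an interferon-inducible gene family with near-identical members, rose (log2 4.95, SE 0.88, adjusted p = 0.037) from very low levels. Its counts were 90, 16, 28 and 14 in the libraries labelled overexpression and 0, 2, 0 and 2 in wild type, a ratio of 34.8 with a 95% Poisson interval of 13.3 to 129, and it is uncertain because the counting may divide reads among family members. All 6 are values of 4 libraries against 4 by edgeR.

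On GRCm38, Kcnj2 (ENSMUSG00000041695) lies on chromosome 11 at 111066164 to 111076821, Tfrc (ENSMUSG00000022797) on chromosome 16 at 32608920 to 32632794, and Xdh (ENSMUSG00000024066) on chromosome 17 at 73883895 to 73950196. Btg2 (ENSMUSG00000020423) lies on chromosome 1 at 134075170 to 134079120, Fosb (ENSMUSG00000003545) on chromosome 7 at 19302696 to 19310051, and Ifi209 (ENSMUSG00000043263) on chromosome 1 at 173630917 to 173647928. Kcnj2 passed the threshold whichever single library was left out. Pairs of libraries labelled overexpression were left out after seeing the data. Without 2 and 3, which leaves the libraries with raised Ino80e, Kcnj2 missed the threshold (log2 -0.60, SE 0.11, adjusted p = 0.12). Without 2 and 4 it missed too (log2 -0.65, SE 0.12, adjusted p = 0.076). It passed without every other pair, among them 1 and 4 (log2 -0.77, SE 0.11, adjusted p = 0.0047). Without overexpression replicate 1 there were 2 calls (Kcnj2 and Btg2), without replicate 2 there was 1, without replicate 3 there were 2 and without replicate 4 there were 8, and without any 1 wild-type library only Kcnj2 was called. Over the 8 fits with a single library left out, Kcnj2 had an adjusted p of 3.7e-04 to 0.043, and Tfrc, Btg2, Fosb, Xdh and Ifi209 each passed in 1, with highest adjusted p of 0.22, 0.22, 0.25, 0.24 and 0.26. Ifi209 missed the threshold without overexpression replicate 1, which holds 90 of its 148 counts in that group (log2 3.98, SE 0.95, adjusted p = 0.26). DESeq2 called 44 genes, 27 of them higher, and limma-voom called 2. On simulated data DESeq2 made 32 false calls, edgeR 7 and limma-voom 10, each beside many true calls. The simulation was a single run with noise drawn from edgeR's own dispersions, so these counts do not rank the methods. Nor do they give the share of false calls among the 44 genes of DESeq2. At an unadjusted p under 0.05 edgeR gave 1883 genes, 925 higher and 958 lower, where 5% of the genes tested is 882, and 811 after a GC correction chosen after seeing the data.

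Genes of activated microglia, microglia and reactive astrocytes were higher in the libraries labelled overexpression by camera's preset test. The median log2 fold change was 0.21 for 20 activated microglia genes (adjusted p = 2.8e-07), 0.21 for 26 microglia markers (adjusted p = 2.6e-05) and 0.22 for 25 reactive astrocyte genes (adjusted p = 3.1e-05). With an estimated correlation these calls were lost (adjusted p = 0.34, adjusted p = 0.73 and adjusted p = 0.41 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 8 activated microglia genes rose, among them the class II antigen presentation genes H2-Eb1 (log2 0.95, SE 0.25) and H2-Ab1 (log2 1.16, SE 0.30) and the receptor tyrosine kinase gene Axl (log2 0.21, SE 0.063). In the microglia list 7 rose adjusted over the list alone, including Lyz2 (log2 0.69, SE 0.17), Fcer1g (log2 0.45, SE 0.15) and Cd68 (log2 0.33, SE 0.12), and Fcrls, named after its values were seen, fell (log2 -0.22). Of the reactive astrocyte list, the complement gene C4b and the intermediate filament gene Vim (log2 0.29, SE 0.077) rose adjusted over the list alone. C4b stood at 48.1 ± 11.7 CPM against 21.1 ± 1.33 CPM (SD, n = 4 each), a log2 fold change of 1.19 (SE 0.18), and missed the threshold over all genes in edgeR with robust estimation (adjusted p = 0.19). It passed in edgeR without robust estimation (adjusted p = 7.3e-04), with no low-count filter (adjusted p = 0.027), without overexpression replicate 3 (adjusted p = 7.3e-09), in DESeq2 (adjusted p = 3.6e-06) and in limma-voom (adjusted p = 0.010). Over 25 alternatives, those chosen after seeing the data included, C4b passed in 9, with adjusted p from 1.1e-09 to 0.67. Other genes of the same mouse complement family can share its reads. Without wild-type replicate 2 the median of the reactive astrocyte list was 0.14, with no low-count filter that of the activated microglia list was 0.36, and without overexpression replicate 2 that of the microglia list was 0.12. The microglia list stood high in replicates 1 and 2 of the group labelled overexpression: its mean shifts were 0.25, 0.36, 0.029 and 0.017 in replicates 1 to 4, against -0.10 to 0.068 in wild type. Without replicates 1 and 2, a pair left out after seeing the data, its median was 0.013 and the call was lost (adjusted p = 0.88). General astrocyte markers did not pass (median log2 0.032, adjusted p = 0.45) but did without wild-type replicate 3 (adjusted p = 0.0063, higher).

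Interferon-stimulated and antigen presentation genes were higher as a list, with all 35 tested members above 0 and a median log2 fold change of 0.29 (camera adjusted p = 4.4e-07, and adjusted p = 0.73 with an estimated correlation). No member passed over all genes or adjusted over the list alone. H2-D1 had a log2 fold change of 0.39 (SE 0.10) and Gbp7 of 0.38 (SE 0.16). Overexpression replicate 1 had the highest level of 34 of the 35 members, and its mean shift was 1.37 on the log2 scale against 0.22, -0.22 and 0.15 in the other libraries labelled overexpression. Without that library the median was 0.010 and the call was lost (adjusted p = 0.47), and without overexpression replicate 3 the median was 0.48.

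Activity-regulated immediate early genes were lower as a list of 30 (median log2 -0.077, camera adjusted p = 1.1e-04, and adjusted p = 0.73 with an estimated correlation). Over all genes 2 members fell, Btg2 and Fosb, and adjusted over the list alone 5 fell, including Ptgs2 (log2 -0.48, SE 0.11) and the neurotrophin gene Bdnf (log2 -0.29, SE 0.095). The libraries labelled overexpression did not move alike: mean shifts were -0.38 and -0.54 in replicates 1 and 2 and 0.074 and 0.12 in replicates 3 and 4, against -0.086 to 0.097 in wild type. Without replicate 2 the median was 0.041 (adjusted p = 0.43), and the medians without replicates 1, 3 and 4 were -0.031, -0.16 and -0.18. Without replicates 1 and 2, a pair left out after seeing the data, the list passed camera as higher (median 0.14, adjusted p = 0.0010). Heat shock and unfolded protein response genes were lower (27 genes, median log2 -0.070, adjusted p = 0.0044, and adjusted p = 0.73 with an estimated correlation), and 4 fell adjusted over the list alone: Hsp90b1 (log2 -0.22, SE 0.056), Dnaja1, Hspd1 and Hspa5. That call was lost without overexpression replicate 4 (adjusted p = 0.055).

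Cytosolic ribosomal protein genes were higher by a small amount, with 67 of 78 members above 0 and a median log2 fold change of 0.090 (camera adjusted p = 6.2e-13, and adjusted p = 0.73 with an estimated correlation). None passed over all genes, and 11 rose adjusted over the list alone, including Rplp2 (log2 0.28, SE 0.057), Rps16 (log2 0.27, SE 0.061) and Rpl35a (log2 0.32, SE 0.086). Many ribosomal protein genes have processed copies in the genome, so their counts are uncertain. Nuclear oxidative phosphorylation genes were also higher (73 genes, median log2 0.041, adjusted p = 0.014, and adjusted p = 0.73 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone; Cox7c had a log2 fold change of 0.37 (SE 0.094). This call was lost without overexpression replicate 2 (adjusted p = 0.21) or 3 (adjusted p = 0.22), and without wild-type replicate 2 (adjusted p = 0.22) or 3 (adjusted p = 0.053); without overexpression replicate 4 the median was 0.074. The 12 mitochondrially encoded genes were lower (median log2 -0.20, adjusted p = 6.3e-04, and adjusted p = 0.73 with an estimated correlation), with mt-Co1 at log2 -0.28 (SE 0.11) and no member past either threshold. Mitochondrial transcripts took 3.46% to 4.18% of counts in the libraries labelled overexpression and 3.79% to 5.05% in wild type, and without wild-type replicate 2 the median of the list was -0.12. Its mean shifts were 0.13, -0.19, -0.28 and -0.35 in the libraries labelled overexpression, against -0.21 to 0.21 in wild type. The call was lost without overexpression replicates 2 and 3, 2 and 4, or 3 and 4, pairs left out after seeing the data. Glucocorticoid-responsive genes were higher (18 genes, median log2 0.091, adjusted p = 0.024, and adjusted p = 0.34 with an estimated correlation), with the metallothionein gene Mt1 at log2 0.24 (SE 0.077) and no member past the threshold over all genes or adjusted over the list alone. Without overexpression replicate 2 (adjusted p = 0.061) or wild-type replicate 1 (adjusted p = 0.052) that call was lost, and without overexpression replicate 4 its median was 0.15. The mean shifts of the glucocorticoid list were 0.066 to 0.19 in the libraries labelled overexpression, against -0.0080 to 0.011 in wild type.

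The mouse genes next to Ino80e that correspond to the human 16p11.2 interval were higher as a list, with 23 of 24 members above 0 and a median log2 fold change of 0.11 (adjusted p = 2.6e-05, and adjusted p = 0.34 with an estimated correlation). Kctd13 had a log2 fold change of 0.17 (SE 0.054) and Coro1a of 0.15 (SE 0.057), and no member passed over all genes or adjusted over the list alone. These genes are rich in GC (median transcript GC 56.3%), and GC-rich transcripts were higher in general in the libraries labelled overexpression. Over 11326 genes of at least 5 CPM, the rank correlation of fold change with GC content was 0.66, which describes genes and not independent replicates. The slope per 10 points of GC of log2 CPM, taken from each gene's mean over the 8 libraries, was higher by 0.12 in the libraries labelled overexpression (0.061 ± 0.027 against -0.061 ± 0.067, SD, n = 4 each; exact permutation p = 0.0286, two-sided, the smallest possible). Subtracting that mean makes the 2 group means opposite in sign, so only their difference is informative. The slope test was not among the tests fixed before the data were examined. After a GC correction chosen after seeing the data, the neighbour list had a median of 0.013 (adjusted p = 0.19) and the mitochondrially encoded list one of -0.053 (adjusted p = 0.57). Tfrc lost its call (log2 -0.19, SE 0.057, adjusted p = 0.70, from -0.31, SE 0.055), and the other 5 genes passed.

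**Figure D2:**
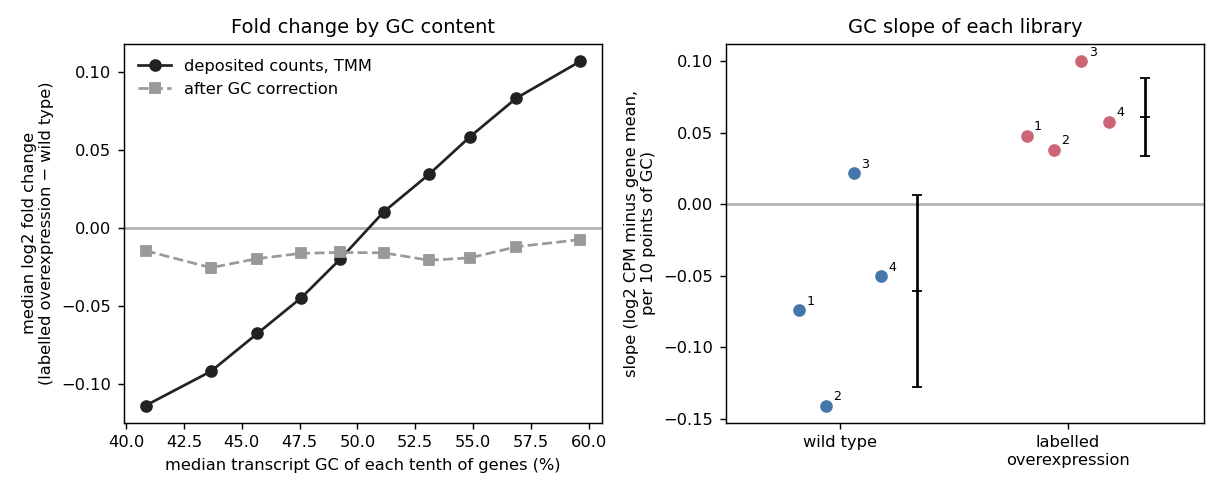
Left, median log2 fold change of genes in 10 groups of equal size by transcript GC content (%), before and after the GC correction. Right, the slope per 10 points of GC of log2 CPM minus the mean of each gene over the 8 libraries, in each library, with the mean ± SD of 4 libraries in black. The median went from -0.11 in the group poorest in GC to 0.11 in the richest, and wild-type replicate 3 was the wild-type library nearest to the group labelled overexpression, with a slope of 0.022.

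Synaptic and neuronal gene lists did not pass the test. This held for glutamate receptors and postsynaptic density (46 genes, median log2 -0.011, adjusted p = 0.79), the presynaptic release machinery (33 genes, median 0.034 with a mean and test direction below 0, adjusted p = 0.98) and dendritic spine and actin regulators (40 genes, median -0.031, adjusted p = 0.19). It also held for GABAergic neuron genes (adjusted p = 0.61), dopamine and serotonin signalling (adjusted p = 0.69), upper-layer markers (adjusted p = 0.10), deep-layer markers (adjusted p = 0.17) and the schizophrenia exome risk genes of the SCHEMA study (10 genes, median -0.016, adjusted p = 0.20). Some of these misses turned on 1 library. Upper-layer markers passed as lower without overexpression replicate 1 (adjusted p = 0.0078) or 3 (adjusted p = 0.021) and without wild-type replicate 1 (adjusted p = 0.039) or 4 (adjusted p = 0.0037). Without wild-type replicate 4 the spine list also passed as lower (adjusted p = 0.045) and deep-layer markers as higher (adjusted p = 0.032). Adjusted over the list alone, no glutamate, presynaptic, spine, GABAergic, dopamine and serotonin or upper-layer gene passed. Grik5 stood at log2 0.15 (SE 0.050), Homer1 at -0.17 (SE 0.061), Erc2 at -0.14 (SE 0.050), Cdc42 at -0.19 (SE 0.053) and Fmr1 at -0.17 (SE 0.056). The signs of Grik5 (GC 60.8%), Homer1 (GC 42.0%) and Erc2 (GC 46.5%) are those of the GC trend, which was not taken out of these values. Adjusted over the list alone, the autophagy gene Rb1cc1 fell in the exome list (log2 -0.25, SE 0.068) and the deep-layer gene Rprm rose (log2 0.23, SE 0.068). After the GC correction the glutamate (adjusted p = 0.021), spine (adjusted p = 0.015) and upper-layer (adjusted p = 0.017) lists passed as lower, with medians of -0.035, -0.036 and -0.069, and none of these passed with an estimated correlation.

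The other subunits of the INO80 complex did not shift as a list (15 genes, median log2 0.042, adjusted p = 0.52), although the mixed test of fry, which counts changes in either direction, gave adjusted p = 0.0069. Adjusted over the list alone, Uchl5, a deubiquitinase of the complex, fell (log2 -0.26, SE 0.069). Uchl5 is poor in GC (41.7%), and GC-poor transcripts were lower in general in the libraries labelled overexpression. The mixed test was not run after the GC correction, so the GC trend and a change of the subunits cannot be told apart. Other chromatin remodelling ATPase families did not pass (adjusted p = 0.12). They passed as lower without wild-type replicate 1 (adjusted p = 0.0061) and after the GC correction (adjusted p = 0.023), also with the replicate block. With all libraries and no GC correction, Smarca5, the ISWI ATPase, fell adjusted over the list alone (log2 -0.23, SE 0.059). The p53 and DNA damage genes (adjusted p = 0.52) and circadian clock genes (adjusted p = 0.69, median below 0 and mean above 0) did not pass.

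Markers of other cell types and of neighbouring tissue varied between libraries. Meningeal and fibroblast genes were higher in the libraries labelled overexpression (20 genes, median log2 0.16, adjusted p = 3.8e-04, and adjusted p = 0.73 with an estimated correlation), and Fbln1 (log2 0.46, SE 0.097) and Mgp (log2 0.54, SE 0.12), both of the extracellular matrix, rose adjusted over the list alone. The median of that list was 0.076 without wild-type replicate 1 and 0.26 without wild-type replicate 3. Its mean shifts were 0.31, 0.10, 0.016 and 0.15 in the libraries labelled overexpression, against -0.18 to 0.19 in wild type, and the call was lost without replicates 1 and 2 (adjusted p = 0.054) or 1 and 4 (adjusted p = 0.15), pairs left out after seeing the data. Choroid plexus markers were lower (13 genes, median log2 -0.90, adjusted p = 0.014, and adjusted p = 0.73 with an estimated correlation), but this rested on wild-type replicate 4, whose mean shift was 2.91. Without it the median was 0.044 (adjusted p = 0.33), without overexpression replicate 2 or 4 the call was also lost (adjusted p = 0.053 and adjusted p = 0.060), and without wild-type replicate 1 the median was -1.37. Kl, a choroid plexus gene, stood at 67.9 CPM in wild-type replicate 4 and at most 8.26 CPM elsewhere. Striatal neuron markers did not pass (adjusted p = 0.10) but ranged from a mean shift of -1.08 in overexpression replicate 1 to 0.99 in overexpression replicate 4, and from -0.81 to 0.66 in wild type; Ppp1r1b had a log2 fold change of 0.32 (SE 0.25). Endothelial and mural markers did not pass as a list (adjusted p = 0.79, median and mean below 0 and test direction above 0), with Slc2a1 (log2 0.16) up and Rgs5 (log2 -0.17) and Kdr (log2 -0.26) down when adjusted over the list alone. Oligodendrocyte genes (adjusted p = 0.52), oligodendrocyte precursors (adjusted p = 0.79), lymphocytes (adjusted p = 0.79), thalamic neurons (adjusted p = 0.61) and blood cells (adjusted p = 0.082) did not pass. With 1 library left out, striatal markers passed as higher without overexpression replicate 1 (adjusted p = 9.2e-10) or wild-type replicate 1 (adjusted p = 0.022) or 4 (adjusted p = 4.5e-04), and blood cell genes as lower without wild-type replicate 1 (adjusted p = 0.0061) or 2 (adjusted p = 0.010). Oligodendrocyte genes passed as higher without overexpression replicate 1 (adjusted p = 0.0018) and as lower without overexpression replicate 2 (adjusted p = 0.030) or wild-type replicate 2 (adjusted p = 0.012), and endothelial markers as higher without wild-type replicate 3 (adjusted p = 0.040). Lymphocyte markers passed as higher with no low-count filter (adjusted p = 0.045), and striatal markers as higher with the replicate block (adjusted p = 0.0496).

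**Figure D3:**
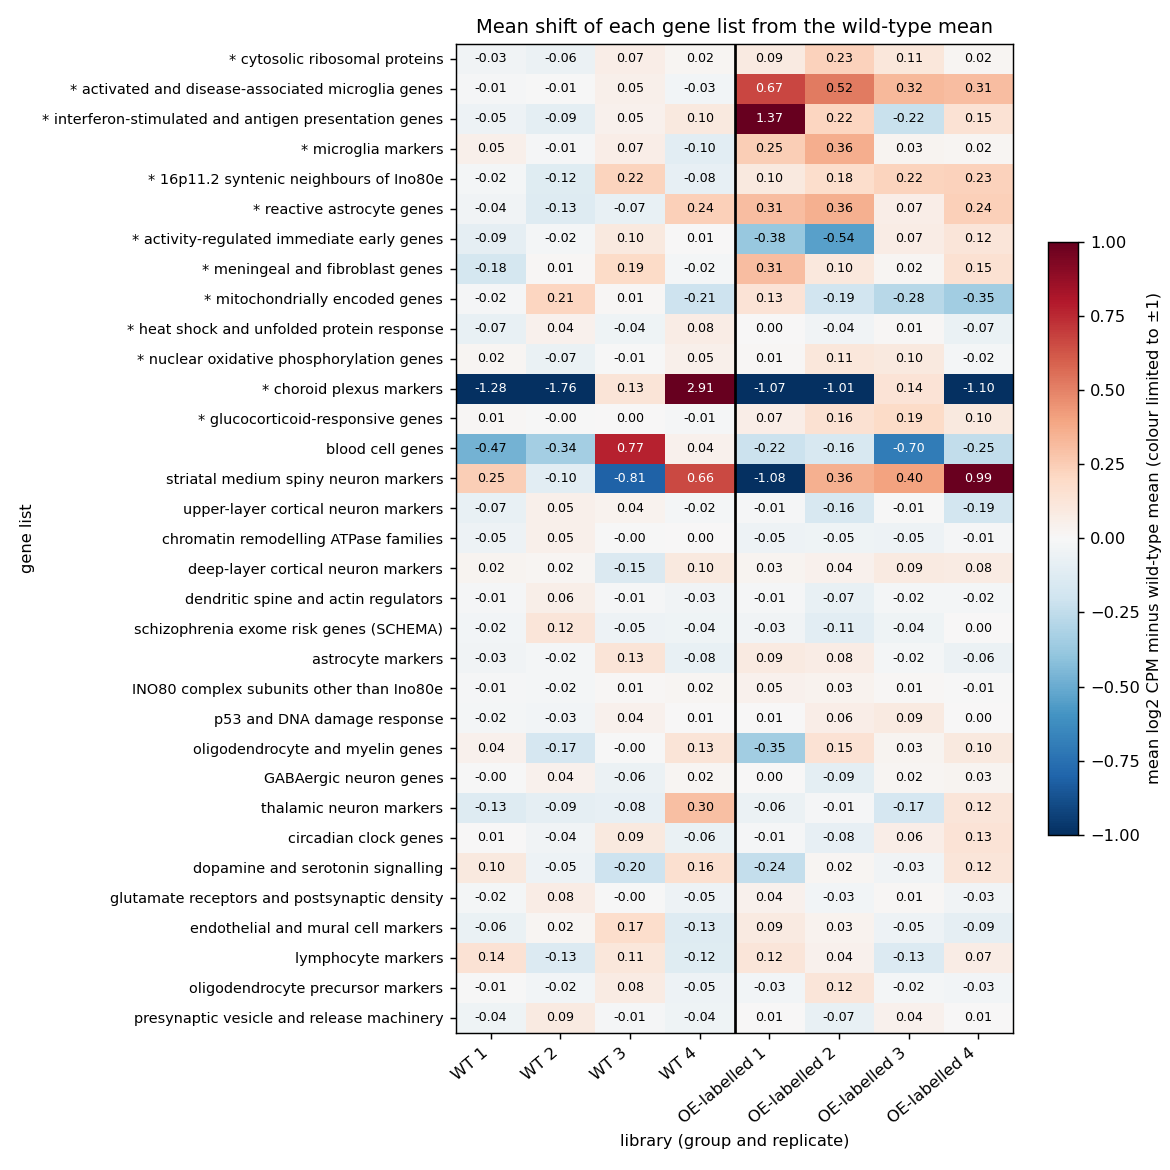
Mean log2 CPM of each gene list in each library, minus the wild-type mean, with wild-type libraries on the left, libraries labelled overexpression (OE) on the right, and an asterisk at the 13 lists that passed camera's preset test. Activated microglia genes and glucocorticoid-responsive genes were above every wild-type library in all 4 libraries labelled overexpression. The interferon shift stood mainly in replicate 1 of that group and the choroid plexus shift in wild-type replicate 4.

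In all, 13 of 33 lists passed camera with the preset correlation, 9 higher and 4 lower. None passed with an estimated correlation and none passed the directional test of fry, while 5 passed its mixed test.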

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

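The tests of swapped labels and striatal dilution, those of a wrong label by gene lists and by C4b, and the test without overexpression replicate 1 were chosen after the results were seen. The counts of genes called in single libraries, the lymphocyte test and the counts over other splits were chosen before their results were seen. Of 178 groups of 4 libraries checked for a library far from the other 3, over 56 named genes and 33 lists, 20 had one, where chance gives about 1 in 20. Ttr, Irf7, Oasl2 and Fcrls were named after their values were seen, and without them 15 of 170 groups had one.

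In the libraries labelled overexpression, replicate 1 stood apart in 3 interferon-inducible genes: Ifi209 (1.73 CPM, next 0.463), Irf7 (15.7 CPM, next 2.79) and Oasl2 (22.0 CPM, next 5.18). Replicate 2 was high in Rpl35a (58.9 CPM, next 47.5) and in the oligodendrocyte precursor list (mean shift 0.12 on the log2 scale), and low in the spine list (-0.074). Replicate 3 was high in Ttr (90.6 CPM, next 7.91) and in the choroid plexus list (0.14), and low in the blood cell list (-0.70) and in Slc2a1 (91.2 CPM, next 93.3). Replicate 4 was high in the chromatin remodelling list (-0.015, next -0.046). In wild type, replicate 4 was high in the choroid plexus genes Ttr (982 CPM, next 90.8) and Kl (67.9 CPM, next 8.26), in the thalamic list (0.30) and in Slc2a1 (87.6 CPM, next 82.5), and low in Ptgs2 (11.1 CPM, next 14.2). Replicate 1 was low in Fosb (14.8 CPM, next 17.3) and high in Fcrls (32.3 CPM, next 27.4), replicate 2 was high in the SCHEMA list (0.12), and replicate 3 was high in Axl (70.7 CPM, next 61.0).

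Ino80e was raised in only 2 of the 4 libraries labelled overexpression, and a swap of labels between the groups is argued against, since it needs a wild-type library at the raised level and the highest wild-type library held 25.5 CPM against 45.04 CPM in the lower raised library. Dilution by striatal tissue as the sole reason is argued against too. To bring Ino80e from the lower raised level to within 1 wild-type SD above replicates 2 and 3, it would leave 17.4% of the cortex. That is a log2 fall of cortical layer markers by 2.52, and the lowest layer list shift in these libraries was -0.16. Replicate 1, with the most Ino80e, did have the lowest striatal shift (-1.08). Replicate 4, the other raised library, had the highest (0.99), above replicates 2 and 3 (0.36 and 0.40). Wild-type tissue under a wrong label stays open for replicates 2 and 3: of the 11 lists called without both, replicate 2 lay beyond the wild-type range in the called direction by more than the wild-type SD in 5 and replicate 3 in 1, activated microglia genes, whose shifts were 0.52 and 0.32 (highest wild type 0.050), and 1 library against 4 is too few to settle it. This was the last of 5 tests of a wrong label, of which a t test on the same lists, where replicate 2 passed and replicate 3 did not, is not used with so few libraries: reactive astrocyte genes did not decide (0.36 and 0.066, wild type to 0.24), C4b went against it (55.7 and 32.8 CPM, wild type at most 22.2), and genes called in single libraries against 3 of wild type (12 to 46 and 3 to 13) stayed under the 74 of wild-type replicate 4 but not all under the 0, 1 and 5 of the others. A weak or missed injection, and wild-type tissue handled apart from these 4 libraries, stay open too and were not tested.

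The interferon list as a whole was higher in the group labelled overexpression mainly because of replicate 1: the mean log2 fold change of the list was 0.38 with that library and 0.048 without it. Not every member followed this. H2-D1, named for a low p, stood at 69.6, 58.4, 49.2 and 49.3 CPM in replicates 1 to 4, against 40.3 to 46.9 CPM in wild type. The lymphocyte shift of replicate 1, 0.12, lay within the range of the other 7 libraries, which reached 0.14. Only 10 of the 28 lymphocyte markers were tested, and the low-count filter removes markers present in 1 library alone. Lymphocytes brought in with that library therefore stay open. A response to the virus, to Ino80e (highest in the same library) or to an unrelated infection may each give such a shift, and with 1 library none of these could be tested.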

How the results depend on the processing

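The GC correction and leaving out pairs of libraries were chosen after the data were seen; the other settings were chosen before. The count of 6 changed genes (2 higher, 4 lower) was the same with both other scalings and at an adjusted p under 0.1, and no scaling moved the median of all genes by over 0.1. It became 83 (55 higher, 28 lower) with no filter, 44 (27 and 17) with DESeq2, 2 (1 and 1) with limma-voom, and 2 (1 and 1) without robust estimation. With an absolute log2 fold of at least 1 it was 1 (1 and 0), while the stricter filter left 1 gene higher and 1 surrogate variable gave 4 higher. Leaving out single libraries gave 1 to 8 changed genes, 0 to 4 higher and 1 to 4 lower, with fewer libraries tested. Without overexpression replicates 1 and 2 there were 11 (9 and 2), without 1 and 3 there were 3 (1 and 2), without 2 and 3 there was 1 (1 and 0), without 2 and 4 there were 3 with 1 lower, and without 3 and 4 there were 23 (14 and 9). Without 1 and 4, the libraries with raised Ino80e, there were 6 (3 and 3). Of these only Kcnj2 and Btg2 were among the 6 of the main test. The 1 gene called without 2 and 3 was C4b, so the libraries with raised Ino80e alone gave none of the main test's genes. The GC correction gave 5 genes, all among the 6 of the main test. Beyond the library or gene numbers that a setting changes by construction, the cause was not tested.

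With the replicate block the count was 1 (0 higher, 1 lower: Kcnj2), and 1 gene was higher with the GC correction and replicate block. The numbers do not pair the libraries: correlations of same-numbered libraries were -0.051, -0.043, 0.015 and 0.027, and no library labelled overexpression correlated best with its own number.

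Ino80e stayed above 0 and did not pass the threshold in any setting, with log2 fold changes from 0.085 (without overexpression replicates 1 and 4) to 1.43 (without 2 and 3), and from 0.47 to 1.11 with a single library left out. The 13 lists became 0 with an estimated correlation and 0 with fry, and 10 to 17 in the other settings. The GC correction called 17, with 11 of the 13 among them, and also blood cell, chromatin remodelling, glutamate, spine and upper-layer lists as lower and striatal markers as higher. The direction of camera's test on a list reversed in 7 cases, given here with the list medians: the interferon list without overexpression replicates 1 and 2 (-0.033), immediate early genes without 1 and 2 (0.14), nuclear oxidative phosphorylation without 2 and 3 (-0.00215), choroid plexus without wild-type replicate 4 (0.044, and from -1.37 to 0.044 over single libraries left out), and oligodendrocyte genes without overexpression replicate 1 (0.083, and from -0.064 to 0.083 over single libraries), 1 and 3 (0.12) and 1 and 4 (0.078). A change of direction with no call on either side was not counted. In 4 more cases the median changed sign while the direction of the test did not: immediate early genes without overexpression replicate 2 (0.041), circadian genes without 1 and 2 (0.058), and endothelial genes without wild-type replicate 3 (0.11) and without overexpression replicates 3 and 4 (0.087). Among single named genes, 46 values gained and 80 lost a call, 3205 did neither and none reversed; among lists 42 gained and 59 lost one. At 4 libraries a group, edgeR found 84% of simulated 1.5-fold changes, but with many genes changed at once, which eases the adjusted threshold. With the few calls of these data that share does not carry over. Smaller differences can be missed and larger ones too: C4b at log2 1.19 (SE 0.18) did not pass (edgeR adjusted p = 0.19).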

Other observations

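The GC correction was chosen after the GC trend was seen, the test of transcript length after its result was seen, and the count of immediate early genes outside the wild-type range after the list shifts were seen; the tests of what the correction does to the lists, and the counts over other splits, were chosen before their results were seen.

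The immediate early genes divided the libraries labelled overexpression. In replicates 1 and 2, 19 and 25 of 30 members lay below all 4 wild-type libraries, and in replicates 3 and 4, 14 and 13 lay above all of them, where chance gives 20% in each direction. Fosb, Btg2, Ptgs2 and Bdnf were below every wild-type library in all 4 libraries labelled overexpression. They were named for a low p in the group test, which favours such genes, so this does not set them apart from the division. Oligodendrocyte and striatal genes were lowest in overexpression replicate 1, with mean shifts of -0.35 and -1.08.

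GC-rich transcripts were higher in the libraries labelled overexpression, with a rank correlation of 0.66 between fold change and GC content. Transcript length in its place is argued against by a partial rank correlation with length of -0.011 once GC is held fixed. The GC trend as the whole cause of the list calls is argued against, because 11 of the 13 lists stayed past camera's preset threshold in the same direction after the correction, although none passed with an estimated correlation. Some medians shrank: nuclear oxidative phosphorylation from 0.041 to 0.016, meningeal genes from 0.16 to 0.099 and microglia markers from 0.21 to 0.14. Others grew, such as that of immediate early genes from -0.077 to -0.15. For the ribosomal shift it stays open: the median fell from 0.090 to 0.059 on the log2 scale, between the bounds set for and against it. The corrected list still passed camera's preset test (adjusted p = 1.7e-12) and missed with an estimated correlation (adjusted p = 0.50). A difference in library preparation between the groups may produce such a trend and the labels name no batch, so preparation and group cannot be separated.

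Chance cannot be excluded for any of these counts. Over the 35 ways to split the 8 libraries into 4 and 4, the real one included, 3 gave at least the 6 changed genes of the real split, and the highest other gave 16. For genes higher (2 in the real split) 4 splits gave as many and the highest other gave 10, and for genes lower (4) 3 splits did and the highest other gave 10. For gene lists past camera's preset threshold (13) 20 splits gave as many and the highest other gave 21, so a list count of this size is common among these libraries whatever the grouping. The split with 16 genes set overexpression replicate 1 and wild-type replicates 1, 2 and 3 against the rest. It differs from the labels only in overexpression replicate 1 and wild-type replicate 4, so whether it shows a structure apart from the labels cannot be told from the count. Its sides also follow the striatal list, with mean shifts of -1.08 to 0.25 against 0.36 to 0.99. Whether striatal tissue in the dissection gave these calls was not tested.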
